A study of Homo sapiens with 6 samples.

How the data were processed

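The deposited table held read counts per gene or locus for 6 libraries of OVCA433 cells, 3 labelled U2AF2 SINC and 3 labelled U2AF2 SI. Per the labels' protocols, total RNA was enriched for poly(A) RNA with oligo(dT) beads, fragmented, and made into strand-specific libraries by dUTP incorporation and removal of the marked strand, followed by PCR. CASAVA and StringTie are named in the submitters' processing notes without versions or roles. The aligner, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The counts deposited by the authors were whole numbers that summed to a different total in each library and were used as raw counts, with no normalization by the authors assumed. PCR reads without molecular identifiers are not independent molecules, so bounds from counts cover counting error only.

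Each count column was tied to a library by the sample descriptions alone, which give the columns with the letter S to the libraries labelled U2AF2 SINC and those with the letter N to the libraries labelled U2AF2 SI, and 0 columns were left without a sample. The table had 11957 rows, named by a gene symbol (11249), an Ensembl identifier (121) or a locus name of the StringTie assembly (587). Every row had a mean of at least 31 counts per library, so rows of low counts were not analysed here, and a list member without a row was not analysed here either. Older symbols were looked up in a gene name table. Library totals ran from 43333966 to 48976810 counts, and the biological coefficient of variation was 27.0%. Libraries of a group were compared by a chi-square of their counts over rows, which ran from 56.0 to 170 per degree of freedom, so no pair was a repeat of 1 library.

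Differences were tested with edgeR 4.0.16 in R 4.3.3 as libraries labelled U2AF2 SI minus libraries labelled U2AF2 SINC, over all 6 libraries, with group as the only term. TMM factors were used, rows were kept by filterByExpr (all 11957 were kept), and glmQLFit and glmQLFTest gave the p-values, which were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values are the deposited counts scaled by TMM-adjusted library size, given as mean ± SD over 3 libraries. A single value was compared by a 2-sided exact permutation test. A fold against a group at 0 was bounded with a floor of 3 counts over the group.

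Gene lists, 37 in all, were fixed before the data were examined, as were the design, the rule for named genes and most of the alternative settings. The 33 lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, and the p-values were adjusted over the lists. Beside it, camera with a correlation estimated per list called 0 of the 33 lists, and fry called 0 by its direction test and 0 by its mixed test. The lists covered splice site recognition, the core spliceosome, SR and hnRNP proteins, nonsense-mediated decay targets, small nucleolar RNA host genes, intronless and histone genes, immediate early genes, p53 targets, apoptosis, S phase, G2 and mitosis, homologous recombination, MYC targets, stress and heat shock responses, interferon, antigen presentation and inflammatory genes, epithelial and mesenchymal genes, TGF-beta, Wnt and YAP targets, ovarian carcinoma markers, sterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ferroptosis, autophagy, and markers of fibroblasts, leukocytes and endothelium. Members were also adjusted over the list alone.

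Named genes were U2AF2 and U2AF1, the 8 largest changes in each direction among rows that passed with a mean of at least 10 CPM and no overlap between groups (0 rows met this), and up to 3 members of each list with the smallest adjusted p, ties going to the larger fold change. HERC3, ENSG00000138641, VIM, TAGLN, KRT8 and KRT18, and the genes named for single alternatives, were chosen after their values were seen. A single gene that the rule names is not reported here.

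The alternative settings chosen beforehand were RLE and upper-quartile scaling, library size alone, no filter, a mean of at least 5 CPM, the replicate number as a block, the omission of each library in turn, DESeq2 1.42.0, limma-voom, an estimated correlation, fry, and camera on ranks. Alternatives added after the data were seen merged 16 Ensembl rows with the row of the same symbol, left out assembled loci, took DESeq2 without independent filtering, or removed a loess trend (span 0.3) on transcript length and then GC content within each library. Lengths and GC content were those of the longest protein-coding transcript of a gene in GENCODE release 29, or of its longest transcript where none was protein-coding. They were found for 94.7% of rows and 99.6% of rows named by a symbol or an Ensembl identifier. The tests were run first on simulated counts with 200 changed genes in each of 5 runs, drawn from the means and sizes of these libraries. The share of unchanged rows called was 0.0735%, and the core spliceosome list, lowered 1.5-fold, was recovered in 5 of 5 runs. Each gene was drawn independently, so these runs could not test list calls where genes vary together. Figures were drawn with matplotlib 3.10.9.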

Results

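OVCA433, an established human ovarian cancer cell line, was profiled by poly(A)-enriched, strand-specific RNA sequencing in 2 groups of 3 libraries, labelled U2AF2 SINC and U2AF2 SI. The series asks how a deficiency of U2AF2 alters gene expression in ovarian cancer cells. U2AF2 encodes the large subunit of the splicing factor that binds the polypyrimidine tract ahead of the 3′ splice site. The labels expand neither abbreviation, so both groups are named as labelled, and every fold change is given as libraries labelled U2AF2 SI against libraries labelled U2AF2 SINC. The libraries held 43333966 to 48976810 counts each over 11957 rows, of which 11249 carried a gene symbol and 587 were loci assembled by StringTie without a gene name. A single assembled locus, MSTRG.23601, took 13.5% ± 2.56 (SD, n = 3) of the counts in libraries labelled U2AF2 SI and 17.3% ± 1.71 (SD, n = 3) in those labelled U2AF2 SINC. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

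U2AF2 itself was measured first, because the groups are named for it. It stood at 335 ± 44.7 CPM (SD, n = 3) in the libraries labelled U2AF2 SI and at 247 ± 39.6 CPM (SD, n = 3) in those labelled U2AF2 SINC, 26.1% lower in the latter. The ranges did not overlap, with 285 to 373 CPM in the former and 205 to 284 CPM in the latter. A 2-sided exact permutation test gave p = 0.1, the smallest p that 3 libraries against 3 can give. In edgeR's quasi-likelihood test the log2 fold change was 0.44 ± 0.19 (SE), with a 95% interval of 0.02 to 0.86, and the Benjamini-Hochberg adjusted p over all rows was 0.653. The lower U2AF2 level was thus in the libraries labelled U2AF2 SINC, and each direction given for the labelled groups carries that limit. U2AF1, which encodes the small subunit of the same factor, was at 59.6 ± 12.01 CPM (SD, n = 3) in libraries labelled U2AF2 SI and 73.1 ± 14.3 CPM (SD, n = 3) in those labelled U2AF2 SINC (log2 fold change -0.29, edgeR adjusted p = 0.739).

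**Figure D1:**
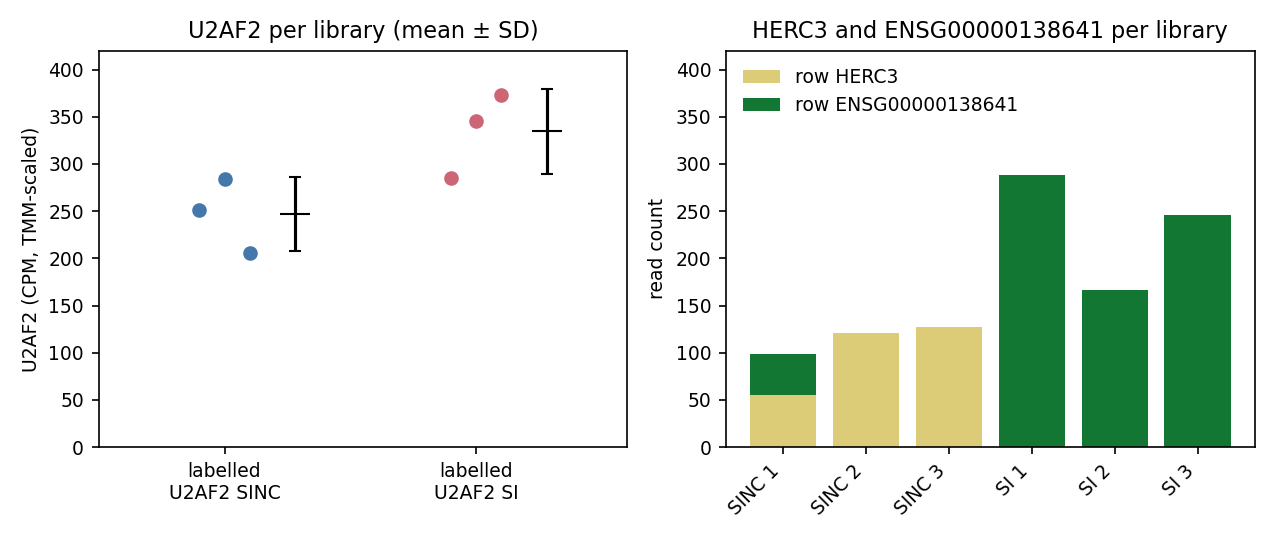
Left, U2AF2 in CPM (TMM-scaled) for each of the 6 libraries (points), with the mean and SD of each labelled group of 3 (black); libraries labelled U2AF2 SI lie between 285 and 373 CPM and those labelled U2AF2 SINC between 205 and 284 CPM. Right, stacked read counts of the rows HERC3 and ENSG00000138641 in each library; the HERC3 row is at 0 in the 3 libraries labelled U2AF2 SI, and the other row is at 0 in replicates 2 and 3 labelled U2AF2 SINC.

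Over all genes, 1 of 11957 rows differed between the groups in edgeR. That row was HERC3, a member of the HERC family of ubiquitin ligases, and it was lower in the libraries labelled U2AF2 SI (edgeR adjusted p = 0.0381). It held 0 counts in all 3 of those libraries and 55, 121 and 127 counts in the libraries labelled U2AF2 SINC, which makes it at least 112-fold lower against a floor of 3 counts over the group, a bound that covers counting error only. The row was named after its values were seen, since its mean of 1.17 CPM lay under the 10 CPM asked of named genes. A further row, ENSG00000138641, which the gene name table pairs with the symbol HERC3, held 288, 167 and 246 counts in libraries labelled U2AF2 SI and 44, 0 and 0 in those labelled U2AF2 SINC (log2 fold change 3.83 ± 1.09 SE, edgeR adjusted p = 0.653). Summed, HERC3 and ENSG00000138641 gave 4.92 ± 1.34 CPM (SD, n = 3) and 2.69 ± 0.346 CPM (SD, n = 3), a log2 fold change of 0.87 with an edgeR adjusted p of 0.654, so that the direction turned and 0 rows passed in edgeR (880 at an unadjusted p under 0.05). The gene name table gives the symbol HERC3 to 2 Ensembl genes, so whether both rows count the same gene was not settled. The HERC3 call also ended under upper-quartile scaling and with library size alone (edgeR adjusted p = 0.0794 and 0.294). It ended without replicate 2 or replicate 3 labelled U2AF2 SINC (0.0674 and 0.125) and without replicate 1 or replicate 2 labelled U2AF2 SI (0.0995 and 0.186).

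No other named gene passed over all rows. At an unadjusted p under 0.05 there were 881 rows, 377 higher and 504 lower in libraries labelled U2AF2 SI, where 598 would come by chance. That count changed with the libraries included. It was 410 without replicate 1 and 384 without replicate 2 labelled U2AF2 SINC, both under the number expected. Without replicate 3 labelled U2AF2 SINC it was 1721 (884 higher, 837 lower), and with the replicate number as a block it was 548. With library size alone, which moved the median log2 fold change of all rows from 0.04 to 0.22, that split was 948 higher and 201 lower. DESeq2 called 61 genes, 60 of them lower in libraries labelled U2AF2 SI, among the 1062 rows to which its independent filtering gave an adjusted p, and 4 over every row it tested; limma-voom called 1. The groups did not overlap in 1559 rows, 13.04% of all, where chance gives 10%. In data simulated from these libraries the edgeR test recovered 89.4% of 4-fold, 37.2% of 2-fold and 3.88% of 1.5-fold changes.

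Of the lists of splicing and RNA processing genes, that of the hnRNP proteins passed the test. Of 33 measured genes for hnRNP and related RNA-binding proteins, 31 lay above 0 and the list was higher in libraries labelled U2AF2 SI (median log2 fold change 0.23, camera adjusted p = 0.000548 at a preset correlation of 0.01). The adjusted p was 0.399 with an estimated correlation. Their transcripts were long, with a median of 4173 nt, and with a trend on transcript length and GC content removed the median was 0.11 and the camera adjusted p 0.0119. Its members with the smallest p were SYNCRIP (0.61 ± 0.26 SE), HNRNPM (0.49 ± 0.19 SE) and HNRNPU (0.43 ± 0.19 SE). The 15 genes of 3′ splice site recognition had a median of -0.06 (camera adjusted p = 0.66), and SF3B6, a component of the SF3B complex, had a log2 fold change of -0.63 ± 0.23 (SE). The 56 core spliceosome genes divided into 25 above and 31 below 0 (median -0.02, camera adjusted p = 0.3). At an unadjusted p under 0.05 there were 18 of these 56, 7 higher and 11 lower in libraries labelled U2AF2 SI, against 7.37% of all rows. Camera tests for a shared direction, so it could hardly call a list divided both ways. The 3 named, with ties in adjusted p going to the larger fold change, were SNRPD2 at -0.82 ± 0.25 (SE), SNRPG at -0.83 ± 0.30 (SE) and LSM7 at -0.71 ± 0.22 (SE). Transcripts of SNRPD2 and LSM7 were short, at 901 and 575 nt. PRPF8, of the same list and named after its values were seen, had 7445 nt and a log2 fold change of 0.58. With the trend on length and GC content removed, the list median was 0.06 (camera adjusted p = 0.811). Among 22 genes for SR proteins and their kinases (median 0.06, camera adjusted p = 0.745), SRRM1 stood at 0.69 ± 0.20 (SE) and SRRM2 at 0.51 ± 0.20 (SE). The 19 measured nonsense-mediated decay targets (median -0.08) and the 25 intronless genes (median 0.06), which include ZXDB at 0.94 ± 0.40 (SE), did not pass either, with camera adjusted p of 0.637 and 0.531. None of these members passed over all rows or adjusted over the list alone, and each gene named here had an edgeR adjusted p of 0.653 over all rows.

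Ribosomal proteins, nuclear genes of oxidative phosphorylation and replication-dependent histones had the smallest camera p, and their medians were lower in libraries labelled U2AF2 SI. All 78 cytosolic ribosomal protein genes had a log2 fold change below 0 (median -0.52, camera adjusted p = 5.5e-28, adjusted p = 0.399 with an estimated correlation), and 42 of them had an unadjusted p under 0.05. RPL39 was at 370 ± 99.4 CPM (SD, n = 3) against 655 ± 168 CPM (SD, n = 3), and RPL35A had a log2 fold change of -0.80 ± 0.27 (SE). Of the 53 nuclear genes encoding subunits of the respiratory chain and ATP synthase, 51 lay below 0 (median -0.46, camera adjusted p = 1.2e-15, adjusted p = 0.399 with an estimated correlation), with NDUFA1 at -1.04 ± 0.32 (SE), ATP5F1E at -0.91 ± 0.31 (SE) and COX7B at -0.90 ± 0.27 (SE). Of the 34 measured histone genes, 33 lay below 0 (median -0.76, camera adjusted p = 1.7e-16, adjusted p = 0.399 with an estimated correlation); H4C11 and H2AC11 had log2 fold changes of -1.29 ± 0.40 (SE) and -1.23 ± 0.46 (SE). Their levels were low, with H4C11 at 1.38 ± 0.486 CPM against 3.36 ± 0.647 CPM (SD, n = 3 each). H2AC11 was at 0.827 ± 0.357 CPM against 1.94 ± 0.295 CPM (SD, n = 3 each). The libraries were enriched for poly(A) RNA, so histone RNA without a poly(A) tail was selected against and total histone RNA was not measured. Histone genes share sequence between near-identical copies, as ribosomal protein genes do with their pseudogenes, so single members are uncertain. The difference lay in replicates 1 and 2 of both groups. Median deviations of these from the mean of the 6 libraries, on the log2 scale, were -0.39 and -0.31 in libraries labelled U2AF2 SI against 0.44 and 0.39 in those labelled U2AF2 SINC for ribosomal protein genes, -0.32 and -0.26 against 0.36 and 0.33 for oxidative phosphorylation genes, and -0.27 and -0.96 against 0.58 and 0.52 for histones. Replicate 3 lay at -0.05, -0.0044 and 0.14 in the former and at -0.05, -0.05 and -0.0077 in the latter for the 3 lists, in the same order. List means per library overlapped between the groups for oxidative phosphorylation and histone genes (exact permutation p = 0.2 for both, 0.1 for ribosomal protein genes). Over all rows 0 members of any of the 3 passed, and adjusted over the list alone 16 oxidative phosphorylation genes, 0 ribosomal protein genes and 0 histone genes did.

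These 3 lists hold short transcripts, with median lengths of 1176, 1257 and 642 nt for ribosomal protein, oxidative phosphorylation and histone genes, and libraries differed along transcript length. In the 1133 genes with the shortest transcripts (median 1088 nt), replicate 1 labelled U2AF2 SI lay -0.37 from the mean of the 6 libraries on the log2 scale, and replicates 1 and 2 labelled U2AF2 SINC lay 0.32 and 0.31 from it. The other 3 libraries lay between -0.11 and -0.05. With a trend on length and GC content removed within each library, the medians were -0.23 for ribosomal protein genes, -0.18 for oxidative phosphorylation genes and -0.23 for histones, with camera adjusted p of 1.3e-07, 0.00263 and 0.0119 at the preset correlation.

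**Figure D2:**
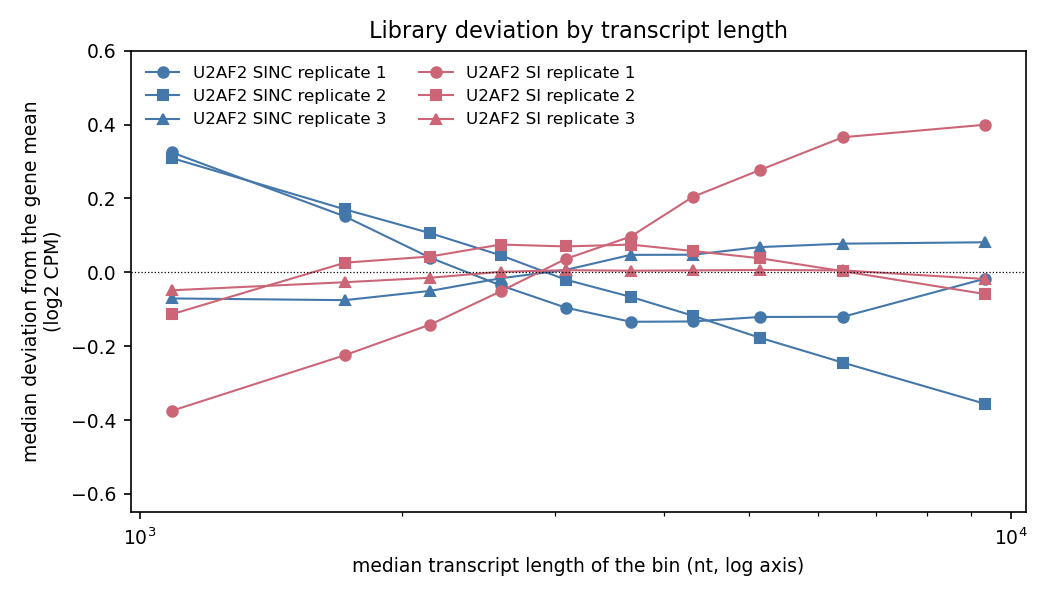
Median deviation of each library from the mean of all 6 (log2 CPM) in 10 equal bins of genes ordered by transcript length (nt, log axis), with 1 line per library. Replicate 1 labelled U2AF2 SI runs from -0.37 to 0.40, replicate 2 labelled U2AF2 SINC from 0.31 to -0.36, and replicate 3 labelled U2AF2 SI stays near 0.

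Genes encoded by the mitochondrial genome went the other way. All 13 lay above 0 (median log2 fold change 1.40, camera adjusted p = 0.000641), 0 passed over all rows and 10 passed when adjusted over the list alone, and with an estimated correlation the adjusted p was 0.679. The value depended on a single library. MT-CYB, which encodes cytochrome b, was at 753 CPM in replicate 2 and 162 CPM in replicate 1 labelled U2AF2 SI. Replicate 3 labelled U2AF2 SI had 60.3 CPM, the lowest of the 6 libraries, and those labelled U2AF2 SINC had 63.3 to 133 CPM (exact permutation p = 0.5). Without replicate 2 labelled U2AF2 SI the median of the mitochondrially encoded genes was 0.35 and the camera adjusted p was 0.435. Their share of all counts was 0.467% ± 0.425 (SD, n = 3) in libraries labelled U2AF2 SI and 0.175% ± 0.079 (SD, n = 3) in those labelled U2AF2 SINC.

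A further 6 lists were higher in libraries labelled U2AF2 SI. Some of them share members, as CCN2 is on both the immediate early and the YAP target list, so these calls are not independent. Fatty acid synthesis genes had 18 of 21 members above 0 (median 0.30, camera adjusted p = 0.00135, adjusted p = 0.399 with an estimated correlation), among them ACLY, which makes cytosolic acetyl-CoA, at 330 ± 24.8 CPM (SD, n = 3) against 242 ± 14.2 CPM (SD, n = 3), and ACACA, acetyl-CoA carboxylase, at a log2 fold change of 0.46 ± 0.20 (SE). Immediate early genes had 21 of 28 above 0 (median 0.23, camera adjusted p = 0.00231, adjusted p = 0.399 with an estimated correlation), with KLF10 at 0.60 ± 0.20 (SE) and SPRY4 at 0.43 ± 0.18 (SE). Among 17 YAP targets (median 0.36, camera adjusted p = 0.0236, adjusted p = 0.399 with an estimated correlation), AMOTL2 was at 62.7 ± 3.15 CPM (SD, n = 3) against 43.1 ± 2.90 CPM (SD, n = 3), NUAK2 at a log2 fold change of 0.72 ± 0.24 (SE) and CCN2 at 0.36 ± 0.15 (SE). The 11 measured Wnt targets had a median of 0.35 (camera adjusted p = 0.0245, adjusted p = 0.399 with an estimated correlation), with CCND1, which encodes cyclin D1, at 98.2 ± 8.90 CPM (SD, n = 3) against 65.04 ± 13.8 CPM (SD, n = 3). S phase genes had 31 of 40 above 0 (median 0.16, camera adjusted p = 0.0315, adjusted p = 0.399 with an estimated correlation), with UHRF1 at 0.50 ± 0.17 (SE), MCM4, a subunit of the replicative helicase, at 0.46 ± 0.18 (SE) and DTL at 0.57 ± 0.22 (SE). Mesenchymal genes had 14 of 21 above 0 (median 0.23, camera adjusted p = 0.0339, adjusted p = 0.399 with an estimated correlation), with COL6A3, a chain of type VI collagen, at 0.84 ± 0.24 (SE) and CDH2, N-cadherin, at 0.93 ± 0.38 (SE). With the trend on length and GC content removed, the medians were 0.17 for fatty acid synthesis, 0.17 for immediate early genes, 0.07 for YAP targets, 0.24 for Wnt targets, 0.08 for S phase and 0.10 for mesenchymal genes, with camera adjusted p of 0.00537, 0.00017, 0.052, 0.0426, 0.0453 and 0.0453. In edgeR 0 of the members of these 6 lists passed over all rows or adjusted over the list alone.

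Several of these calls ended when 1 library was left out, which also leaves fewer libraries to test. Some medians rose where the call ended. Without replicate 3 labelled U2AF2 SINC the median was 0.48 for Wnt targets and 0.39 for YAP targets. It was 0.21 for S phase and 0.26 for mesenchymal genes, while that of immediate early genes fell to 0.18. A lost call thus need not mean that the library left out carried the difference. Fatty acid synthesis, hnRNP, ribosomal protein, oxidative phosphorylation and histone calls passed in all 6 omissions of 1 library, though the fatty acid synthesis median was 0.18 without replicate 1 labelled U2AF2 SINC and the histone median -0.49 without replicate 2 labelled U2AF2 SI. The hnRNP median was 0.15 without replicate 1 labelled U2AF2 SINC and 0.17 without replicate 1 labelled U2AF2 SI. List means per library overlapped between the groups for fatty acid synthesis and hnRNP genes (exact permutation p = 0.2 for both). Immediate early genes had camera adjusted p of 0.0779 without replicate 3 labelled U2AF2 SINC and 0.0606 without replicate 2 labelled U2AF2 SI. YAP targets had 0.0814 without replicate 3 labelled U2AF2 SINC, 0.0667 without replicate 1 labelled U2AF2 SI and 0.052 with the length trend removed; their median was 0.20 without replicate 1 labelled U2AF2 SI and 0.23 without replicate 2 labelled U2AF2 SINC. Wnt targets had 0.0626 and 0.0779 without replicates 1 and 3 labelled U2AF2 SINC and 0.176 without replicate 2 labelled U2AF2 SI. S phase genes had 0.0887 and 0.0814 without replicates 1 and 3 labelled U2AF2 SINC and 0.0561 and 0.255 without replicates 1 and 3 labelled U2AF2 SI, and their median was 0.07 without replicate 1 labelled U2AF2 SI and 0.08 without replicate 2 labelled U2AF2 SINC. Mesenchymal genes had 0.149 and 0.0779 without replicates 2 and 3 labelled U2AF2 SINC and 0.0575 and 0.266 without replicates 2 and 3 labelled U2AF2 SI, and a median of 0.15 without replicate 1 labelled U2AF2 SINC.

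**Figure D3:**
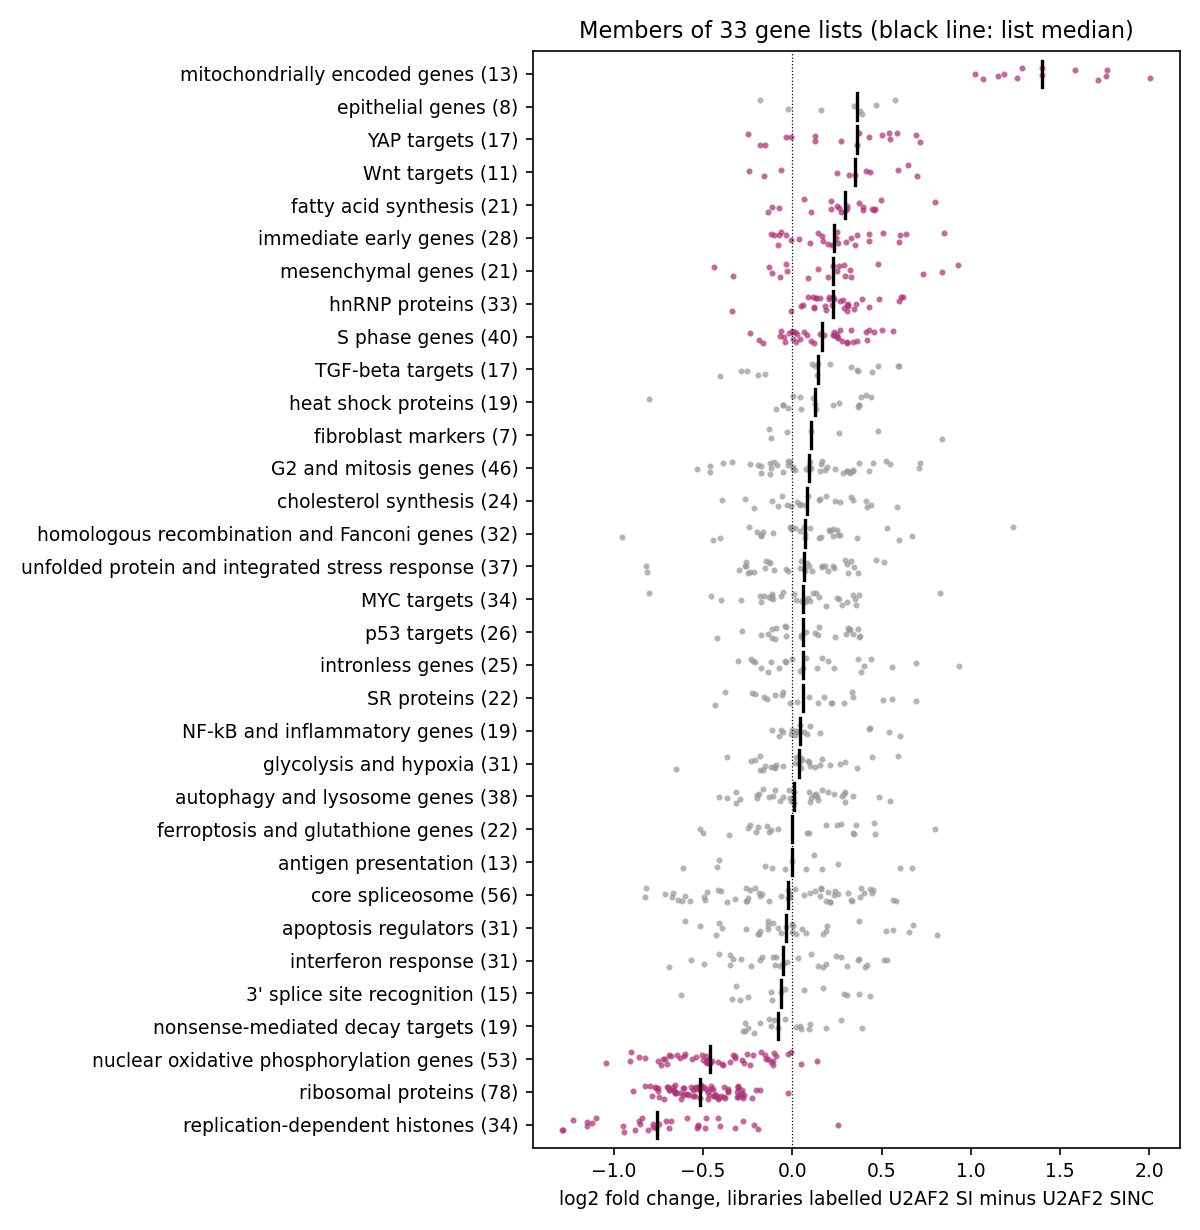
Log2 fold change of each measured member (points) of 33 gene lists, libraries labelled U2AF2 SI minus U2AF2 SINC, with the list median (black line) and the number of measured members in parentheses; lists with a camera adjusted p under 0.05 at the preset correlation are coloured. Ribosomal protein, oxidative phosphorylation and histone members lie almost wholly below 0, with medians of -0.52, -0.46 and -0.76, and the mitochondrially encoded genes above it.

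No list of stress or cell death genes passed. DDIT3, the stress-induced transcription factor CHOP, was at 34.2 ± 3.11 CPM (SD, n = 3) in libraries labelled U2AF2 SI and 60.1 ± 3.69 CPM (SD, n = 3) in those labelled U2AF2 SINC, a log2 fold change of -0.81 ± 0.17 (SE). It was the 1 member of 37 unfolded protein and integrated stress response genes that passed adjusted over the list alone, and over all rows its edgeR adjusted p was 0.653. NUPR1, of the same list, had a log2 fold change of -0.82 ± 0.27 (SE). The list had a median of 0.06 with a camera direction of lower (camera adjusted p = 0.945). Heat shock genes had a median of 0.13 (camera adjusted p = 0.523), with HSPE1, the mitochondrial co-chaperonin, at -0.80 ± 0.23 (SE). Of the 26 p53 targets (median 0.06, camera adjusted p = 0.66), TRIAP1 was at -0.42 ± 0.18 (SE) and TNFRSF10B at 0.38 ± 0.17 (SE). Apoptosis regulators, with CASP2 at 0.52 ± 0.19 (SE), had a median of -0.04 and a mean of 0.01 (camera adjusted p = 0.828).

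Proliferation and repair genes outside S phase did not pass. The 46 genes of G2 and mitosis had a median of 0.09 (camera adjusted p = 0.355), with MKI67 at 0.71 ± 0.27 (SE), ANLN at 0.71 ± 0.28 (SE) and CKS2 at -0.53 ± 0.21 (SE); CKS2 turned to 0.06 with the length trend removed. Homologous recombination and Fanconi genes (median 0.07, camera adjusted p = 0.523) included FANCD2 at 0.60 ± 0.23 (SE). MYC targets had a median of 0.06 (camera adjusted p = 0.945), with UTP20 at 0.83 ± 0.35 (SE).

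The immune lists, and the signalling and metabolic lists not named above as passing, were likewise not called. Medians were -0.05 for interferon response genes (camera adjusted p = 0.993), 0.04 for NF-kB and inflammatory genes (0.355) and 0.14 for TGF-beta targets (0.22). Antigen presentation genes had a median of -0.0019 and a mean of 0.01 (camera adjusted p = 0.828), with PSMB9, an immunoproteasome subunit, at -0.61 ± 0.23 (SE). Cholesterol synthesis genes had a median of 0.08 (0.496) and autophagy and lysosome genes 0.01 (0.993). Glycolysis and hypoxia genes had a median of 0.04 with a camera direction of lower (0.945), HK2 standing at 0.59 ± 0.22 (SE). Ferroptosis and glutathione genes divided into 11 above and 11 below 0, with a median of -0.00061 and a camera direction of higher (0.993).

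Markers of cell identity were measured in part. Of 29 epithelial genes 8 were analysed here (median 0.36, camera adjusted p = 0.207), among them JUP at 0.38 ± 0.17 (SE). Of 28 ovarian carcinoma markers 4 were analysed, too few for a test, and PRAME was at 119 ± 16.4 CPM (SD, n = 3) in libraries labelled U2AF2 SI against 101 ± 15.0 CPM (SD, n = 3). Fibroblast markers, of which 7 were analysed and 5 of these are also on the mesenchymal list, had a median of 0.10 (camera adjusted p = 0.22), and COL6A3 was the 1 member that passed adjusted over the list alone. Leukocyte markers were represented by CORO1A and CD68, at log2 fold changes of -0.07 and -0.01, and endothelial markers by ESAM and EGFL7, at -0.67 and -0.12; with library size alone CORO1A, CD68 and EGFL7 turned to 0.12, 0.18 and 0.07. Of the 18 small nucleolar RNA host genes, 0 were analysed here.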

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

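The merging of rows, the removal of assembled loci, the removal of the length and GC trend and DESeq2 without independent filtering were chosen after the data were seen. U2AF2 kept its direction in all 18 alternatives that gave it a value, at log2 fold changes of 0.32 to 0.62, and its adjusted p, 0.198 to 0.999, passed in none; without 1 library the range was 0.32 to 0.55. RLE scaling, no filter (which removed no row and so tested nothing), limma-voom and the removal of assembled loci kept the count at 1 gene, HERC3. Genes changed, genes lower in libraries labelled U2AF2 SI and genes changed at least 2-fold were each 0 under upper-quartile scaling, library size alone, a mean of at least 5 CPM, merged rows, and with the trend removed. The mean of 5 CPM left out HERC3 by its construction, merging ended its call by its second row (log2 fold change 0.87), and the cause of the others was not tested. Without 1 library, genes changed ran from 0 to 2, genes higher from 0 to 1, genes lower from 0 to 2, genes changed at least 2-fold from 0 to 2, and gene lists called from 6 (without replicate 3 labelled U2AF2 SINC) to 10, with 7 without replicate 2 labelled U2AF2 SI; the 2 genes were HERC3 with ENSG00000138641 (without replicate 1 labelled U2AF2 SINC) or with ENSG00000264058 (without replicate 3 labelled U2AF2 SI).

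DESeq2 called 61 genes, 1 higher and 60 lower, 2 of them at least 2-fold; it gave an adjusted p to 1062 rows and NA to 10895. Without independent filtering it called 4, of which 1 was higher (ENSG00000257524) and 3 lower (HERC3, GAGE12D and DDIT3), 3 of them at least 2-fold, so the larger count came from the smaller number of rows tested. GAGE12D belongs to a family of near-identical copies and is uncertain. With the replicate number as a block, 2 genes changed (HERC3 and ENSG00000257524), 1 higher and 2 at least 2-fold, and 11 lists were called. Libraries of the same number had correlations of -0.09, 0.25 and -0.31 between their deviations from the group means. Only those numbered 2 correlated best with their own number. Replicate 1 labelled U2AF2 SI correlated best with replicate 3 labelled U2AF2 SINC (0.46). Replicate 3 labelled U2AF2 SI correlated best with replicates 1 and 2 labelled U2AF2 SINC (0.14 each). The block is given only as a check.

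The 11 lists called at the preset correlation were 11 under the other 3 scalings, 7 at a mean of at least 5 CPM (mesenchymal, YAP, Wnt and S phase lists were lost), 10 on ranks, 10 with the trend removed, and 0 with an estimated correlation (smallest adjusted p 0.399), by fry's direction test (0.188) and by its mixed test (0.0633). With library size alone the medians were -0.32 for ribosomal protein, -0.27 for oxidative phosphorylation, 0.41 for hnRNP, 0.47 for fatty acid synthesis, 0.42 for immediate early, 0.54 for YAP and for Wnt target, 0.36 for S phase and 0.40 for mesenchymal genes, against -0.52, -0.46, 0.23, 0.30, 0.23, 0.36, 0.35, 0.16 and 0.23. Of 1798 values of other named genes under the alternatives, 1778 kept their sign. With library size alone, which moved the median of all rows to 0.22, CORO1A turned to 0.12, CD68 to 0.18, EGFL7 to 0.068, KRT8 to 0.16 and KRT18 to 0.0062. With the trend removed, CKS2 turned to 0.062, CORO1A to 0.10 and CD68 to 0.11. Without 1 library, CORO1A ran from -0.17 to 0.074, CD68 from -0.050 to 0.065, EGFL7 from -0.55 to 0.13, KRT8 from -0.19 to 0.12 and KRT18 from -0.34 to 0.0065. The cause of these turns was not tested. At 43333966 counts or more per library and a coefficient of variation of 27.0%, 3.88% of simulated 1.5-fold changes were recovered, and depth was not varied on its own; rows near 1 CPM, such as HERC3, rest on few counts.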

Other observations

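Of the tests in this part, the sum of the HERC3 rows, the length trend as the whole of the group shifts, and the exchange of group labels were chosen after the results were seen, as were the genes of the next paragraph.

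Among genes of cell identity, the intermediate filament VIM was at 5428 ± 621 CPM (SD, n = 3) in libraries labelled U2AF2 SI and 4342 ± 410 CPM (SD, n = 3) in those labelled U2AF2 SINC, and TAGLN, an actin-binding protein, at 1369 ± 219 and 1855 ± 263 CPM (SD, n = 3 each). The epithelial keratins were lower in level, with KRT18 at 290 ± 76.4 and 329 ± 72.3 CPM and KRT8 at 42.6 ± 9.80 and 43.3 ± 2.66 CPM (SD, n = 3 each). None of these 4 differed between the groups in edgeR (adjusted p 0.709, 0.672, 0.856 and 0.984). Of the lists fixed beforehand, 21 of 36 mesenchymal genes, 8 of 29 epithelial genes and 4 of 28 ovarian carcinoma markers were analysed here. The identity of the line was taken from the labels and was not checked here.

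The 60 genes that DESeq2 called lower in libraries labelled U2AF2 SI held 18 members of the fixed ribosomal protein list (Fisher's exact test against the 1062 rows with an adjusted p, adjusted p = 1.5e-06) and 8 of the fixed oxidative phosphorylation list (adjusted p = 0.0276). Fisher's test takes genes that vary together as independent, and both lists had a camera adjusted p of 0.399 with an estimated correlation. Of the 61 genes DESeq2 called, 0 were called when it tested every row, and each had an edgeR adjusted p of 0.653. The median transcript length of the 60 was 991 nt, against 2162 nt for those 1062 rows. The 1 gene called higher was PRPF8, the central protein of the spliceosome.

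HERC3 was the 1 row called over all genes, and ENSG00000138641 showed the opposite distribution over the libraries. A candidate explanation is that reads of a single gene were assigned to different rows in different libraries. The 2 rows summed gave a log2 fold change of 0.87 and no call, but this sum restates counts already seen and decides nothing. The summed rows did not overlap between the groups, at 3.37 to 5.77 CPM in libraries labelled U2AF2 SI and 2.31 to 2.99 CPM in those labelled U2AF2 SINC. Open is whether the HERC3 row counts the gene ENSG00000138641 or another gene of that symbol, and a change in transcript use between the groups was not tested.

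The lower ribosomal protein, oxidative phosphorylation and histone lists may in part reflect a trend on transcript length or GC content that differed between libraries. With the trend removed, 44.99%, 40.2% and 30.7% of the 3 medians were left, so the trend may account for the larger part of each. At the preset correlation all 3 lists still passed with the trend removed, the largest camera adjusted p being 0.0119. None of these lists passed with an estimated correlation before the correction. Lengths were those of the longest protein-coding transcript of a gene, such as 5575 nt for UQCRB and 3437 nt for RPS23. That transcript need not be the one expressed here, so what is left cannot tell whether the trend was the whole. A single library deciding the sign of the medians is argued against, since over all omissions of 1 library the median nearest to 0 was -0.34. The histone median still moved from -0.76 to -0.49 without replicate 2 labelled U2AF2 SI. All 3 calls passed in each omission, but at the preset correlation their p were so small that an omission could hardly end them. Replicate 3 of the groups differed little in these lists (-0.05 against -0.05, -0.0044 against -0.05 and 0.14 against -0.0077), so the difference rests on replicates 1 and 2. A difference between the labelled groups stays open for what is left.

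The U2AF2 transcript was lower in the libraries labelled U2AF2 SINC. Scaling between libraries is argued against as the reason, since the log2 fold change under the other 3 scalings was at least 0.42. The columns of the libraries labelled U2AF2 SINC carry the letter S and those of the libraries labelled U2AF2 SI the letter N, letters that alone could be read the other way. Whether group labels or column names were exchanged cannot be told apart from the labels being right, because no value here decides it and the labels do not say which group was depleted of U2AF2; the exact permutation p of 0.1 is the smallest that 3 libraries against 3 can give, and decides nothing. A biological difference between the groups in the other direction was not tested.

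Other splits of the 6 libraries into 3 and 3 are 10 with the real one, too few for a share under 0.05. The real split called 11 gene lists at the preset correlation, which 1 of 10 splits reached, and the highest of the others called 6. It called 1 gene, which 5 of 10 splits reached, and the highest of the others called 3. At an unadjusted p under 0.05 the real split gave 881 rows, and 7 of the 9 others gave fewer, 74 to 866. The splits that set replicates 1 and 2 labelled U2AF2 SINC with replicate 2 or with replicate 3 labelled U2AF2 SI gave more, 1875 and 1715.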
